A study of Mus musculus with 11 samples.

How the data were processed

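PolyA RNA, extracted with the Qiagen RNeasy kit per the labels, was sequenced from mouse cell lines derived from liver tumours with YAP-S127A, YAP-5SA or TAZ-S89A. All 11 libraries of the series were used, each in the group that its label names, and replicates were numbered in the order of deposition. The labels spell the YAP-5SA group differently from the series text, and both spellings were read as the same mutant. The deposited tables hold a count column, which per the file headers gives reads aligning uniquely to each Entrez gene model. The authors aligned reads with GSNAP to the GRCm38 build, per the submitters' processing notes. The aligner version, counting tool, annotation release and strand setting are not given in the sources used here. A further column holds nRPKM, an RPKM adjusted by the authors with a size factor per library, per the file headers. The ratio of counts to nRPKM between any pair of libraries was the same for every gene, so these values added nothing to the counts and were not used in the comparisons.

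The tables list 36528 gene IDs. Symbols and positions were taken from the RefSeq annotation of GRCm38, which matched 31049 of them. The 5479 unmatched IDs held 2.91% of counts and stayed in the library totals. Total counts per library ran from 20071144 to 49159713. Genes that overlap another tested gene, or belong to families of similar sequence, were treated as uncertain, since the strand setting is not known.

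Differences were tested on counts with edgeR 4.0.16 in R 4.3.3. A low-count filter (filterByExpr by group) kept 18224 genes and removed 18304. Libraries were scaled by TMM, and CPM are on that scale. A quasi-likelihood model with robust dispersion was fitted to all 11 libraries with the 3 groups as the only term, so the groups shared an estimate of the spread. Estimated per group, the relative spread between libraries beyond counting error was 0.09 in YAP-S127A, 0.174 in YAP-5SA and 0.246 in TAZ-S89A. The shared estimate therefore carries spread of TAZ-S89A into the comparison of the YAP groups. The contrasts were TAZ-S89A against the mean of the YAP groups and the 3 pairwise comparisons. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. In the pairwise comparisons, fold changes against a group with no counts were computed as lower bounds against a floor of 3 counts over the group. Those against 1 to 3 counts were given as ratios of pooled counts with a 95% interval. Both cover counting error only.

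Before the data were examined, 25 gene lists with 564 symbols, a symbol counted once per list, were written from general knowledge, and 492 of these were tested. They cover YAP/TAZ-TEAD targets, Hippo pathway components, inflammatory cytokines and chemokines, interferon response, hepatocyte, biliary and progenitor, stellate cell, endothelial and macrophage markers, oncofetal liver genes, epithelial and mesenchymal genes, proliferation, cholesterol synthesis, fatty acid synthesis and storage, hypoxia and glycolysis, the Notch, Wnt and TGF-beta and BMP pathways, p53 targets, AP-1 and immediate early genes, NRF2 targets, stress responses, sex-linked and mitochondrially encoded genes. Some genes are in more than 1 list. The 24 lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) and again with an estimated correlation. Adjustment was over the 96 tests of 24 lists in 4 contrasts. With the preset correlation 27 of these were called, and 5 with the estimated correlation.

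The genes named were set by a rule fixed before the data were examined. It takes 10 genes in every comparison (Yap1, Wwtr1, Tead1 to Tead4, Ccn1, Ccn2, Ankrd1 and Amotl2) and up to 4 called members of each list with the largest absolute log2 fold change. It adds the 10 highest and 10 lowest fold changes of the first contrast and the 6 highest and 6 lowest of each pairwise one. Those had to have an average log2 CPM of at least 2, no overlap between the libraries of the sides and a symbol that is not a predicted model. A result that the rule selected but that is withheld is not reported here. Hoxb and Hoxc clusters, their neighbours, Rian, Mirg, Trp53, Cdkn2a, Cd74, Ctss, Apoe and Gapdh, and list members outside the rule, were chosen after their values were seen.

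The alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter and a strict one (at least 1 CPM in at least 3 libraries and an average log2 CPM of at least 1), only the groups compared, the sample ID series as a covariate or without its second part, an absolute log2 fold change of at least 1, and leaving out each library in turn. The second ID series holds TAZ-S89A replicates 4 and 5 only. Leaving out the library of each group that correlates least with the others was added after the data were seen. The analysis was tested on simulated counts drawn with the real means, totals and spread. At a true change of 2-fold it recovered 78% of changed genes in the first contrast, 59.2% for TAZ-S89A against YAP-S127A, 52% for TAZ-S89A against YAP-5SA and 51% for YAP-5SA against YAP-S127A, over 17776, 17744, 17704 and 17705 genes. It called at most 0.07% of unchanged genes, and found the raised list and no other. Genes were drawn independently of each other, so this could not test list calls among correlated genes. Few genes were changed, with 17550 of 17776 unchanged in the first contrast, so the adjusted cutoff was stricter there than in the data. Chromosome medians were computed over 11688 genes with a mean log2 CPM of at least 2, and tested against 10000 gene sets matched on expression. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and the plots.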

Results

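The series holds RNA sequencing of 11 libraries from cell lines of mouse liver cancers, in 3 groups named for the mutant that the tumours carried. YAP (gene Yap1) and TAZ (gene Wwtr1) are related coactivators that switch on genes through the TEAD transcription factors. The kinases of the Hippo pathway phosphorylate both proteins on serines and so hold them outside the nucleus, and each mutant has alanine in place of such serines. YAP-S127A and TAZ-S89A are changed at the single site in their names, and YAP-5SA at further such sites as well. The groups held 3 YAP-S127A, 3 YAP-5SA and 5 TAZ-S89A libraries, and no group without a mutation was analysed here. The labels do not say whether the libraries of a group came from separate tumours, lines or cultures. The p-values therefore measure only the spread between these libraries, which may be technical, and an effect of the mutant cannot be separated from the identity of the line. A count of Yap1 or Wwtr1 cannot tell the gene's own transcript from that of an introduced mutant copy.

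Total counts came to 46243462, 32314692 and 39498516 in YAP-S127A replicates 1 to 3, and 40377647, 49159713 and 42581219 in those of YAP-5SA. TAZ-S89A replicates 1 to 3 held 40009048, 42294516 and 35819107, while replicates 4 and 5, whose sample IDs belong to a second number series, held 20246736 and 20071144. The correlation across genes of log2 CPM, counts scaled to a common library total, ran from 0.939 to 0.998 within TAZ-S89A, from 0.975 to 0.996 within YAP-5SA and from 0.992 to 0.998 within YAP-S127A. Between groups it ran from 0.738 to 0.819, over genes that are not independent replicates. No pair of libraries matched within sampling noise. By a chi-square on counts per degree of freedom, TAZ-S89A replicates 4 and 5 came closest at 2.08, and replicates 1 and 2 stood at 5.98. The other TAZ-S89A pairs ran from 110.05 to 236.35, so these libraries are not equally distinct replicates. Levels below are mean CPM ± SD, with n = 5 for TAZ-S89A and n = 3 for each YAP group. Values in parentheses after a gene are its log2 fold change and standard error (SE) in edgeR's quasi-likelihood fit, and adjusted p-values are Benjamini-Hochberg values.

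The comparison of TAZ-S89A with both YAP groups, weighted equally, addresses how lines from TAZ-driven tumours differ from lines from YAP-driven ones. TAZ-S89A libraries held less Yap1, Tead1, Ccn2 and Amotl2 mRNA, far less of the p53 target Cdkn1a, of the apolipoprotein gene Apob and of the Hoxc genes, and more of the cholesterol synthesis gene Sqle, of Fat4 and of the growth factor gene Hgf. Yap1 (Entrez gene 22601, chromosome 9, 7931999 to 8004638) stood at 66.5 ± 13.7 CPM in TAZ-S89A, 197 ± 11.8 in YAP-S127A and 171 ± 8.44 in YAP-5SA, a log2 fold change of -1.47 (SE 0.15, adjusted p = 1.07e-06). Wwtr1 (Entrez gene 97064, chromosome 3, 57455644 to 57575910) was at 82.3 ± 13.3, 66.4 ± 1.54 and 141 ± 10.9 CPM and was not called at -0.23 (SE 0.12, adjusted p = 0.115). It was called at an adjusted p of 0.0145 without the second ID series and 0.00657 with the series as a covariate (range 0.00657 to 0.323 over 20 alternatives). Tead1 fell to 114 ± 20.6 CPM from 390.1 ± 33.2 in YAP-S127A and 238 ± 31.3 in YAP-5SA, at -1.42 (SE 0.16, adjusted p = 3.71e-06). Of its paralogs, Tead2 was higher at 0.85 (SE 0.09) and Tead4 lower at -0.38 (SE 0.11). Tead3 was not called at -0.24 (SE 0.13, adjusted p = 0.137), but was without YAP-5SA replicate 2 (adjusted p = 0.0137) or the least correlated library of each group (0.0157, range 0.0137 to 0.401 over 20 alternatives).

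Among the canonical targets of the coactivators, Ccn2, a secreted matricellular protein, fell from 708 ± 15.9 CPM in YAP-S127A and 634 ± 15.8 in YAP-5SA to 234 ± 85.6 in TAZ-S89A, at -1.52 (SE 0.23, adjusted p = 5.85e-05). Its relative Ccn1 was lower at -0.77 (SE 0.16) and Amotl2, an angiomotin that binds YAP, at -1.46 (SE 0.16), whereas Ankrd1 was higher at 0.66 (SE 0.11). Within TAZ-S89A the second ID series stood higher for both Ccn genes, though below every YAP library. Ccn2 was at 162, 148 and 213 CPM in replicates 1 to 3 and at 321 and 327 in replicates 4 and 5. Ccn1 was at 212, 195 and 259 CPM against 299.9 and 303. The 22 tested YAP/TAZ-TEAD targets split into 4 higher, 12 lower and 6 not called, and the set test did not call the list (median log2 fold change -0.54, camera adjusted p = 0.221). The ecto-nucleotidase gene Nt5e (-3.24, SE 0.19) and Dock5 (-1.74, SE 0.17) were lower, and Fjx1 (3.15, SE 0.14) was higher. Of 25 Hippo pathway components, 4 rose, 10 fell and 11 were not called (median -0.23, camera adjusted p = 0.317), with Amotl1 (-2.53, SE 0.16) lower and the atypical cadherin Fat4 (2.57, SE 0.14) higher. Yap1, Amotl1, Amotl2 and Nt5e lie on chromosome 9, where the median log2 fold change of all genes was -0.64 against YAP-S127A and -0.57 against YAP-5SA. Tead1 lies on chromosome 7, where these medians were -0.67 and -0.54.

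**Figure D1:**
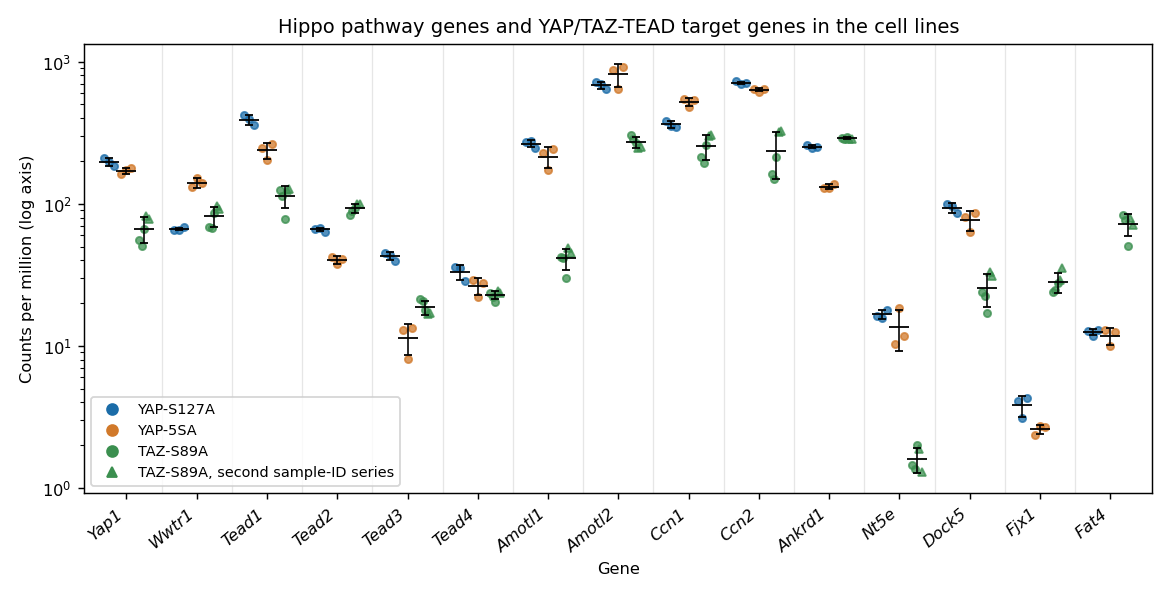
CPM per library on a log axis for Hippo pathway genes and YAP/TAZ-TEAD targets, with each point a library, black dashes the group mean and bars its SD. Mean Yap1 was 66.5 CPM in TAZ-S89A and 197 in YAP-S127A, whereas mean Fat4 was 72.3 and 12.5.

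Several hepatocyte and oncofetal liver genes stood low in TAZ-S89A. Of the 14 hepatocyte markers with enough counts to test, 10 fell, 3 rose and 1 was not called (camera adjusted p = 0.0105, and adjusted p = 0.0987 with an estimated correlation). Apob fell to 2.09 ± 0.567 CPM from 76.8 ± 4.82 in YAP-S127A and 726 ± 46.6 in YAP-5SA, and Fah, the last enzyme of tyrosine breakdown, was lower at -4.97 (SE 0.15). A further 18 hepatocyte markers had too few counts to test, none above a pooled 0.165 CPM in any group. Some tested markers were near the floor too, with Alb at no more than 1.31 CPM and Hp at no more than 32 counts in any library. The list therefore does not show hepatocyte differentiation in the YAP groups. Oncofetal liver genes split into 2 higher, 10 lower and 2 not called of 14 (camera adjusted p = 0.00331, and adjusted p = 0.076 with an estimated correlation). The imprinted zinc-finger gene Plagl1 (-4.93, SE 0.19) and the RNA-binding protein gene Lin28b (-6.02, SE 0.43) were lower. Macrophage and leukocyte markers split into 1 higher, 9 lower and 7 not called of 17 (camera adjusted p = 0.00589, and adjusted p = 0.076 with an estimated correlation), but were not called against YAP-S127A alone (2 higher and 3 lower, adjusted p = 0.641). The lysozyme gene Lyz2 (-4.66, SE 0.30) was lower, from 15.96 ± 4.39 CPM in YAP-5SA and 1.34 ± 0.412 in YAP-S127A. In the list of p53 targets and cell cycle inhibitors, 16 of 22 fell and 4 rose (camera adjusted p = 0.00144, and adjusted p = 0.239 with an estimated correlation). The receptor gene Eda2r (-5.50, SE 0.24), the CDK inhibitor Cdkn1a (-4.89, SE 0.22) and Ccng1 (-2.74, SE 0.21) were lower, and another CDK inhibitor, Cdkn2b (2.78, SE 0.19), was higher. Cdkn1a stood at 5.22 ± 1.86 CPM in TAZ-S89A, 85.8 ± 3.22 in YAP-S127A and 272 ± 11.5 in YAP-5SA.

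Cholesterol synthesis genes rose in 17 of 23 cases and fell in 1 (camera adjusted p = 0.000196, and adjusted p = 0.239 with an estimated correlation). Squalene epoxidase, Sqle (1.39, SE 0.13), and lanosterol demethylase, Cyp51 (1.67, SE 0.22), were both higher, as was the sterol-responsive Insig1 (1.28, SE 0.12). Of 26 proliferation genes, 15 rose and 2 fell (camera adjusted p = 0.0386, and adjusted p = 0.776 with an estimated correlation). The replicative helicase subunits Mcm5 (0.92, SE 0.15) and Mcm4 (0.72, SE 0.19) changed most. Within TAZ-S89A, Mcm4 stood higher in the second ID series, with 4051 and 3877 counts in replicates 4 and 5. Replicates 1 to 3 held 3459, 3609 and 3553, out of larger library totals. The call of the proliferation list was lost without any of 6 single libraries, at 0.069 without TAZ-S89A replicate 3, 0.067 without TAZ-S89A replicate 5, 0.0592 without TAZ-S89A replicate 4, 0.0579 without YAP-5SA replicate 3, 0.0558 without YAP-5SA replicate 1 and 0.0535 without YAP-S127A replicate 1. It was also lost without the second ID series, at 0.0635 (range 0.0129 to 0.069 over 14 alternatives).

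Of the 24 lists with a set test, 18 were not called. Inflammatory cytokines and chemokines had 11 higher and 12 lower of 30 (adjusted p = 0.483), and interferon response genes 13 higher and 10 lower of 29 (adjusted p = 0.937). Biliary and progenitor markers had 6 higher and 9 lower of 22 (adjusted p = 0.503). Epithelial genes had 3 higher and 12 lower of 19 (adjusted p = 0.059). They were called without TAZ-S89A replicate 3 (0.0267), replicate 4 (0.05, rounded up) or replicate 5 (0.0339), in a range of 0.0267 to 0.0959 over 14 alternatives. Mesenchymal genes had 13 higher and 11 lower of 30 (adjusted p = 0.973), and stellate cell markers 4 higher and 4 lower of 8 (adjusted p = 0.566). Endothelial markers had 1 higher and 6 lower of 10 (adjusted p = 0.0891), and fatty acid synthesis and storage genes 7 higher and 3 lower of 16 (adjusted p = 0.406). In the last list the desaturase Scd1 (-8.88, SE 0.20) was at 0.3795 ± 0.129 CPM in TAZ-S89A and 258 ± 8.89 in YAP-S127A. Hypoxia and glycolysis genes had 6 higher and 8 lower of 26 (adjusted p = 0.806), and Wnt pathway targets 4 higher and 11 lower of 17 (adjusted p = 0.155). TGF-beta and BMP pathway genes had 7 higher and 10 lower of 25 (adjusted p = 0.937). Notch pathway genes had 9 higher and 3 lower of 17 (adjusted p = 0.0783), and 0.0468 without TAZ-S89A replicate 3 (range 0.0468 to 0.186 over 14 alternatives). AP-1 and immediate early genes had 4 higher and 13 lower of 23 (adjusted p = 0.162), and 0.0213 without the second ID series (range 0.0213 to 0.268 over 14 alternatives). In that list the ERK feedback inhibitors Spry4 (-6.05, SE 0.36) and Dusp6 (-3.00, SE 0.16) were lower. NRF2 targets had 3 higher and 10 lower of 22 (adjusted p = 0.276). Unfolded protein and amino acid stress genes had 2 higher and 9 lower of 23 (adjusted p = 0.17), and mitochondrially encoded genes 1 higher and 0 lower of 11 (adjusted p = 0.383). The single tested sex-linked gene was not called, and the other 4 had 0 counts. Adjusted over the list alone, 17 of the 25 lists gave the same counts of higher and lower members. The counts became 6 and 10 for biliary, 1 and 7 for endothelial, 8 and 3 for fatty acid, 10 and 3 for Notch, 8 and 10 for TGF-beta, 4 and 17 for p53, 1 and 9 for stress and 0 and 0 for mitochondrially encoded genes. Median and mean log2 fold change or the direction of the test differed in sign for inflammatory (-0.03, 0.31, higher), interferon (-0.01, -0.40, higher), mesenchymal (0.13, -0.61, higher), fatty acid (0.35, -0.41, higher) and TGF-beta genes (0.06, -0.50, lower).

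**Figure D2:**
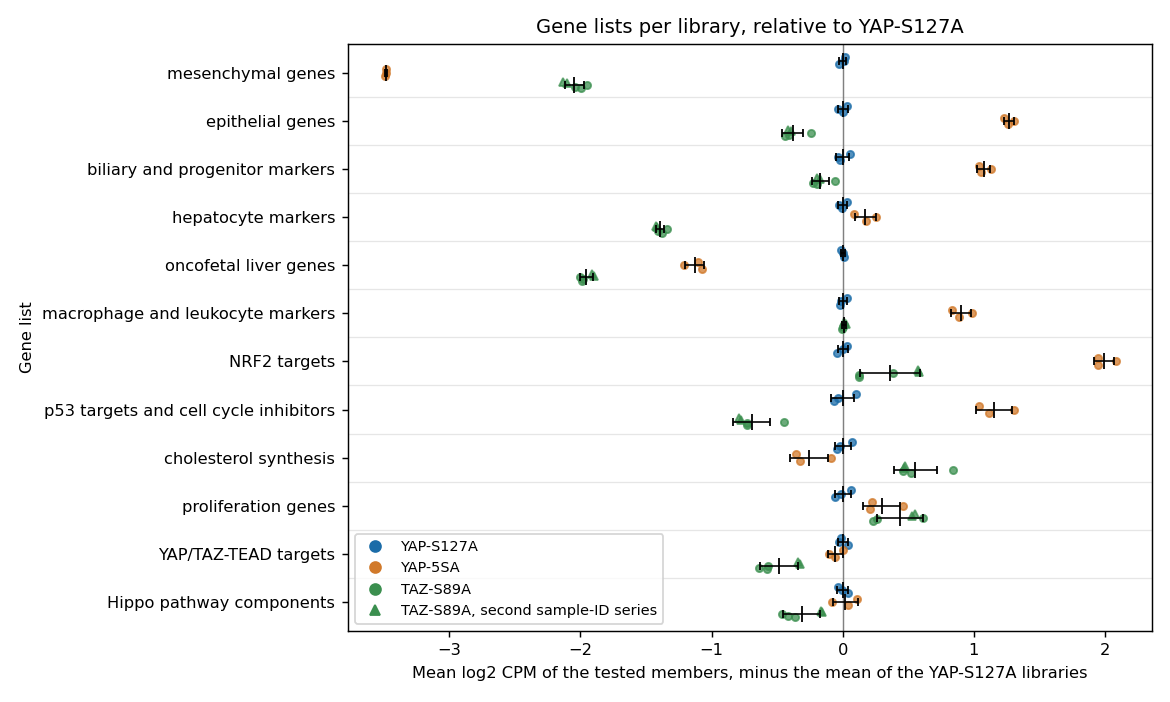
Mean log2 CPM of the tested members of 12 gene lists in each library, minus the mean of the YAP-S127A libraries, with each point a library, black ticks the group mean and bars its SD. Mesenchymal genes stood lowest in YAP-5SA, and the mean of p53 targets was lower in TAZ-S89A than in either YAP group, a difference that camera did not call against YAP-S127A (adjusted p = 0.0642).

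Beyond the lists, the 10 genes with the largest increases under the naming rule included the sulfotransferase Sult1c2 (10.34, SE 0.37), S100g (8.27, SE 0.63), Fam135b (7.90, SE 0.36) and Hgf (7.86, SE 0.24). The other 6 had at most 3 counts in a YAP group, so levels are given in place of a fold. The cornified envelope gene Sprr1b was at 14.6 ± 2.49 CPM in TAZ-S89A, the thyroxine-binding globulin gene Serpina7 at 10.8 ± 7.97, the sodium channel gene Scn3a at 10.04 ± 4.403, the cadherin Cdh22 at 9.81 ± 1.21, the transcription factor Runx3 at 16.3 ± 3.15 and Brinp3 at 30.0 ± 8.22. The second ID series stood apart for Serpina7, at 1.79 and 2.46 CPM in replicates 4 and 5 and 17.7, 17.1 and 14.8 in replicates 1 to 3, and for S100g, at 18.1 and 20.04 against 112, 122 and 86.7. Hgf (Entrez gene 15234, chromosome 5, 16553495 to 16619439), hepatocyte growth factor, was at 44.3 ± 10.4 CPM in TAZ-S89A, 0.581 ± 0.0883 in YAP-S127A and 0.0581 ± 0.0367 in YAP-5SA. The adrenomedullin gene Adm (Entrez gene 11535, chromosome 7, 110627657 to 110629820) was at 88.95 ± 8.49 CPM in YAP-5SA and 23.3 ± 2.09 in YAP-S127A, against 1 count in all TAZ-S89A libraries. Counts were as few for Ano3, at 51.8 ± 2.69 CPM in YAP-5SA and 4.19 ± 0.328 in YAP-S127A, and Anxa10, at 304 ± 128 and 0.728 ± 0.303. No count at all was found in TAZ-S89A for Hoxc10, at 47.1 ± 3.37 CPM in YAP-5SA and 1.73 ± 0.208 in YAP-S127A, Hoxc8 (16.7 ± 0.659 and 1.25 ± 0.124), Rem1 (0.355 ± 0.0316 and 52.0 ± 2.29) and Tmem202 (11.7 ± 3.06 and 8.88 ± 0.825). The engulfment adaptor Gulp1 (-10.64, SE 0.31) and Hoxc6 (-10.34, SE 0.31) were also among the 10 largest decreases. Tmem202 overlaps Hexa, S100g overlaps Ctps2, Cdh22 overlaps Gm36803 and Ano3 overlaps Muc15 in the annotation, so their counts are uncertain, as are those of the similar Sprr and Hox genes.

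In all, 10699 of 18224 tested genes were called by edgeR at an adjusted p under 0.05, 5133 higher and 5566 lower in TAZ-S89A. Of these, 5122 changed by at least 1 on the log2 scale, 1932 upwards and 3190 downwards.

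Against YAP-S127A, the other mutant changed at a single site, the TAZ-S89A libraries held fewer transcripts of mesenchymal and oncofetal genes. Collagen Col1a1 stood at 30.98 ± 3.57 CPM in TAZ-S89A and 2950.1 ± 168 in YAP-S127A, and the receptor gene Pdgfra at 0.146 ± 0.0569 and 102 ± 4.599, while Col1a2 was at 2219 ± 767 and 2274 ± 117. The lists of cholesterol synthesis and proliferation genes were called higher, and hepatocyte markers lower, with the preset correlation but not with an estimated one (0.403, 0.774 and 0.076). Secreted immune factors went both ways (list 0.151), with the interleukin antagonist Il1rn higher (73.3 ± 13.2 CPM against 1.29 ± 0.181) and Il11 (-4.49, SE 0.20), Il6 (-4.58, SE 0.24) and Cxcl12 (-2.31, SE 0.22) lower. Yap1 was lower at -1.57 (SE 0.17, adjusted p = 2.23e-06) and Tead1 at -1.78 (SE 0.18, adjusted p = 1.59e-06).

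Ccn2, at -1.60 (SE 0.26), Amotl2, at -1.34 (SE 0.18), Tead3, at -1.19 (SE 0.15), and Tead4, at -0.54 (SE 0.13), were lower and Tead2, at 0.50 (SE 0.11), was higher. Ccn1 was called lower at -0.51 (SE 0.19, adjusted p = 0.0313), but not without any of 6 libraries, TAZ-S89A replicate 1 (0.0698), 2 (0.0694) or 3 (0.0646) and YAP-S127A replicate 1 (0.109), 2 (0.0743) or 3 (0.0659). The call was also lost with no low-count filter (0.077), with only the groups compared (0.0575) and without the least correlated library of each group (0.0764), in a range of 0.000452 to 0.109 over 21 alternatives. Wwtr1 was not called at 0.31 (SE 0.15, adjusted p = 0.0876), but was without TAZ-S89A replicate 2 (0.042, range 0.042 to 0.349 over 21 alternatives). Ankrd1 was not called at 0.19 (SE 0.14, adjusted p = 0.254) but was by DESeq2 (0.0219, range 0.0219 to 0.443 over 21 alternatives). YAP/TAZ-TEAD targets went 5 up and 14 down of 22 (camera adjusted p = 0.155), with Nt5e (-3.39, SE 0.20) and Rbms3 (-2.50, SE 0.13) lower and Fjx1 (2.87, SE 0.18) higher. Hippo pathway components went 7 up and 11 down of 25 (camera adjusted p = 0.545), with Amotl1 (-2.68, SE 0.17) lower and Fat4 (2.53, SE 0.18) higher.

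Mesenchymal genes fell in 21 of 30 cases and rose in 5 (camera adjusted p = 0.000368, and adjusted p = 0.0454 with an estimated correlation). The homeobox gene Prrx1 (-10.65, SE 0.34), Pdgfra (-9.41, SE 0.19) and lysyl oxidase, Lox (-7.39, SE 0.19), were among the most reduced. Of 14 oncofetal liver genes, 11 fell and 0 rose (camera adjusted p = 0.000196, and adjusted p = 0.0454 with an estimated correlation), among them Peg3 (-7.96, SE 0.21) and Plagl1 (-5.17, SE 0.20). The imprinted transcript H19 was at 3.42 ± 0.292 CPM in YAP-S127A and had no count in TAZ-S89A (at least 192.1-fold lower against a floor of 3 counts over the group). Hepatocyte markers went 10 down and 1 up of 14 (camera adjusted p = 0.0039, and adjusted p = 0.076 with an estimated correlation), with Apob (-5.19, SE 0.22) and Fah (-4.58, SE 0.16) lower and haptoglobin, Hp (4.07, SE 0.66), higher. Hp had only 1, 0 and 3 counts in the YAP-S127A libraries and at most 30 in a TAZ-S89A library. Cholesterol synthesis genes rose in 15 of 23 cases and fell in 1 (camera adjusted p = 0.00483, and adjusted p = 0.403 with an estimated correlation), with Sqle (1.87, SE 0.16), Ebp (1.56, SE 0.18) and Cyp51 (1.49, SE 0.28) higher. Proliferation genes went 14 up and 2 down of 26 (camera adjusted p = 0.0124, and adjusted p = 0.774 with an estimated correlation), with Mcm5 (1.31, SE 0.19) and the kinesin Kif11 (1.08, SE 0.20) higher.

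NRF2 targets, the genes of the oxidative stress response, went 12 up and 3 down of 22 (camera adjusted p = 0.0481, and adjusted p = 0.776 with an estimated correlation), with the transferase Mgst1 (3.92, SE 0.22) higher and Gsta4 (-3.35, SE 0.23) lower. This call was lost without TAZ-S89A replicate 5 (0.081), 4 (0.0704) or 3 (0.0678), YAP-S127A replicate 1 (0.0535) or YAP-5SA replicate 3 (0.0517). It was also lost without the second ID series (0.107), with RLE factors (0.0552) and without the least correlated library of each group (0.0751), in a range of 0.0214 to 0.107 over 14 alternatives. Genes of the unfolded protein and amino acid stress response went 12 down and 1 up of 23 (camera adjusted p = 0.0284, and adjusted p = 0.776 with an estimated correlation). The cystathionine lyase gene Cth (-2.53, SE 0.27) and Trib3 (-1.79, SE 0.20) were lower. That call was lost without YAP-S127A replicate 3 (0.0597), TAZ-S89A replicate 1 (0.0541) or TAZ-S89A replicate 2 (0.0521), in a range of 0.0102 to 0.0597 over 14 alternatives. In all, 17 lists were not called, with adjusted p from 0.0642 to 0.965. Endothelial markers (1 higher, 5 lower and 4 not called) became called without YAP-S127A replicate 3 (0.0362, range 0.0362 to 0.124 over 14 alternatives). P53 targets (4 higher, 14 lower and 4 not called) were called without TAZ-S89A replicate 3 (0.0436) or the least correlated library of each group (0.0401, range 0.0401 to 0.0941 over 14 alternatives), and AP-1 genes (6 higher, 12 lower and 5 not called) without the second ID series (0.0287, range 0.0287 to 0.296 over 14 alternatives). Adjusted over the list alone, 21 of the 25 lists gave the same counts, the exceptions being TEAD targets (5 higher, 15 lower), cholesterol synthesis (16 and 1), fatty acid (8 and 3) and AP-1 genes (6 and 13). Median and mean differed in sign for interferon (0.23, -0.04), biliary (0.08, -0.84), fatty acid (0.45, -0.22) and hypoxia genes (0.17, -0.49), whose tests pointed upwards.

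Sprr1b (at least 538.4-fold higher), Serpina7 (at least 464.5-fold) and Scn3a (at least 339.7-fold) had no count in YAP-S127A. By pooled counts Runx3 was higher by 1736-fold (95% counting interval 311 to 68602, from 1 count) and Brinp3 by 1156-fold (95% counting interval 395 to 5606, from 3 counts). Sult1c2 (Entrez gene 69083, chromosome 17, 53829637 to 53845958) was at 75.7 ± 26.8 CPM against 0.0938 ± 0.0334. In the other direction, the small GTPase Rem1 (Entrez gene 19700, chromosome 2, 152627008 to 152635191) was at 52.0 ± 2.29 CPM in YAP-S127A with no count in TAZ-S89A (at least 2948.2-fold lower), and Tmem202 likewise had none (at least 499.4-fold). The secreted protein gene Cthrc1 (-12.39, SE 0.47), the sphingolipid receptor S1pr3 (-11.62, SE 0.31) and the metalloprotease Adam19 (-11.30, SE 0.31) were lower. S1pr3 overlaps Gm32834, so its count is uncertain. EdgeR called 10505 genes, 4926 higher and 5579 lower in TAZ-S89A, 5873 of them by at least 1 on the log2 scale.

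Against YAP-5SA, the TAZ-S89A libraries held less of macrophage markers and of Krt7, Krt8 and Krt19. The lists of p53 and NRF2 targets were called lower, and cholesterol synthesis genes higher, with the preset correlation but not with an estimated one (0.192, 0.325 and 0.292). Keratin Krt19 stood at 7.39 ± 2.76 CPM in TAZ-S89A and 1372 ± 339.7 in YAP-5SA, and Krt7 at 1.41 ± 0.673 and 1744 ± 434. Col1a2 went the other way, at 2219 ± 767 CPM against 16.2 ± 1.56, as did the receptor gene Pdgfrb at 268 ± 37.2 against 1.12 ± 0.112, but Col1a1 was lower, at 30.98 ± 3.57 against 322 ± 57.2. The p53 ubiquitin ligase gene Mdm2 was at 86.7 ± 15.5 CPM against 1217 ± 309. Yap1, at -1.36 (SE 0.17), Wwtr1, at -0.77 (SE 0.14), Tead1, at -1.06 (SE 0.18), Ccn1, at -1.03 (SE 0.19), Ccn2, at -1.44 (SE 0.26), and Amotl2, at -1.59 (SE 0.18), were all lower. Ankrd1, at 1.13 (SE 0.14), Tead2, at 1.21 (SE 0.12), and Tead3, at 0.71 (SE 0.16), were higher, and Tead4 was not called at -0.21 (SE 0.13, adjusted p = 0.171).

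YAP/TAZ-TEAD targets went 7 up and 13 down of 22 (camera adjusted p = 0.375), with Nt5e (-3.09, SE 0.20) and Igfbp3 (-2.35, SE 0.20) lower and Rbms3 (5.51, SE 0.23) and Fjx1 (3.44, SE 0.18) higher. Hippo pathway components went 3 up and 12 down of 25 (camera adjusted p = 0.271), with Amotl1 (-2.37, SE 0.17) and Ptpn14 (-1.80, SE 0.17) lower. Of 19 epithelial genes, 13 fell and 2 rose (camera adjusted p = 0.00483, and adjusted p = 0.076 with an estimated correlation), including Krt8 (-6.63, SE 0.33) and the membrane protease St14 (-7.73, SE 0.40). Mesenchymal genes rose in 16 of 30 cases and fell in 7 (camera adjusted p = 0.0263, and adjusted p = 0.117 with an estimated correlation), with Pdgfrb (7.90, SE 0.25), Col1a2 (7.10, SE 0.40) and periostin, Postn (6.58, SE 0.22), higher. Hepatocyte markers went 9 down and 2 up of 14 (camera adjusted p = 0.0284, and adjusted p = 0.148 with an estimated correlation), with Apob (-8.43, SE 0.24), Fah (-5.36, SE 0.16) and the urea cycle gene Ass1 (-5.35, SE 0.34) lower. Macrophage and leukocyte markers went 13 down and 1 up of 17 (camera adjusted p = 0.000519, and adjusted p = 0.0454 with an estimated correlation). The complement genes C1qa (at least 143.1-fold lower), C1qb (at least 83.8-fold) and C1qc (at least 77.2-fold) had no count in TAZ-S89A.

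NRF2 targets fell in 17 of 22 cases and rose in 0 (camera adjusted p = 0.000196, and adjusted p = 0.325 with an estimated correlation), among them the quinone reductase Nqo1 (-5.05, SE 0.24), the epoxide hydrolase Ephx1 (-3.31, SE 0.18) and Gsta4 (-6.08, SE 0.25). In the p53 list, 17 of 22 fell and 2 rose (camera adjusted p = 0.000196, and adjusted p = 0.192 with an estimated correlation), with Eda2r (-6.53, SE 0.26), Cdkn1a (-5.72, SE 0.24), Mdm2 (-3.81, SE 0.21) and Fas (-3.79, SE 0.20) lower. Cholesterol synthesis genes went 15 up and 2 down of 23 (camera adjusted p = 0.000738, and adjusted p = 0.292 with an estimated correlation), with Insig1 (2.14, SE 0.16), Cyp51 (1.85, SE 0.28) and Dhcr7 (1.72, SE 0.14) higher. In all, 17 lists were not called, with adjusted p from 0.059 to 0.999. Oncofetal liver genes (3 higher, 9 lower and 2 not called) became called without YAP-5SA replicate 2 (0.0398, range 0.0398 to 0.0744 over 14 alternatives). Mitochondrially encoded genes (2 higher, 0 lower and 9 not called) were called without TAZ-S89A replicate 3 (0.019) or the least correlated library of each group (0.0284, range 0.019 to 0.343 over 14 alternatives), and AP-1 genes (6 higher, 14 lower and 3 not called) without the second ID series (0.038, range 0.038 to 0.283 over 14 alternatives). Adjusted over the list alone, 16 of the 25 lists gave the same counts of higher and lower members. The others became 3 and 9 for hepatocyte, 4 and 9 for oncofetal, 2 and 14 for epithelial, 1 and 8 for endothelial, 2 and 13 for macrophage, 0 and 0 for proliferation (from 6 and 2), 5 and 12 for hypoxia, 3 and 8 for Wnt and 1 and 0 for mitochondrially encoded genes. Median, mean and test differed in sign for inflammatory (-0.09, 0.01, higher), fatty acid (0.08, -0.61, higher) and TGF-beta genes (-0.08, -0.17, higher).

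The zinc-finger gene Bnc2 (at least 546.6-fold higher) and the imprinted noncoding RNA gene Airn (at least 233.7-fold) had no count in YAP-5SA. The transcriptional coactivator Eya4 (10.52, SE 0.40) and Sult1c2 (11.01, SE 0.54) were higher too. By pooled counts Cdh22 was higher by 1204-fold (95% counting interval 216 to 47588, from 1 count) and the kinase Hunk by 1138-fold (95% counting interval 204 to 44986, from 1 count). The annexin gene Anxa10 (Entrez gene 26359, chromosome 8, 62057042 to 62123193) was at 304 ± 128 CPM in YAP-5SA and had 1 count in TAZ-S89A, a ratio of 52072 with a 95% counting interval of 9345 to 2056800.0. Adm had a ratio of 15155 (2719 to 598630.0). Hoxc10 (at least 2661.8-fold lower), Hoxc13 (at least 1377.9-fold), Cpxm2 (at least 1812.3-fold) and the carboxylesterase Ces2f (at least 1333.2-fold) had no count in TAZ-S89A. Airn overlaps Igf2r, and Ces2f has close relatives, so both counts are uncertain. EdgeR called 10545 genes, 4898 higher and 5647 lower in TAZ-S89A, 6164 of them by at least 1 on the log2 scale.

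The comparison of YAP-5SA with YAP-S127A asks how lines with a more fully unphosphorylatable YAP differ from lines with the single change. The YAP-5SA libraries held less of 26 of 30 mesenchymal transcripts and more Krt18 and Krt19. The lists of NRF2 and p53 targets were called higher with the preset correlation but not with an estimated one (0.186 and 0.239). The smooth muscle gene Tagln stood at 2.36 ± 0.767 CPM in YAP-5SA and 1264 ± 267 in YAP-S127A, Pdgfrb at 1.12 ± 0.112 and 474 ± 31.3, and Col1a2 at 16.2 ± 1.56 and 2274 ± 117, while Col1a1 still stood at 322 ± 57.2 against 2950.1 ± 168. Krt18 was at 2820.3 ± 527 CPM against 164 ± 20.2, and Krt19 at 1372 ± 339.7 against 55.9 ± 8.47. Aldh3a1, an aldehyde dehydrogenase (Entrez gene 11670, chromosome 11, 61208510 to 61218418), was at 1687 ± 455 CPM against 0.642 ± 0.271. Yap1 itself was not called at -0.20 (SE 0.19, adjusted p = 0.385), nor were Ccn2 at -0.16 (SE 0.29, adjusted p = 0.67) and Amotl2 at 0.25 (SE 0.21, adjusted p = 0.323).

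Wwtr1 was higher at 1.08 (SE 0.16), while Tead1, at -0.71 (SE 0.21), Tead2, at -0.71 (SE 0.13), Tead3, at -1.91 (SE 0.18), and Ankrd1, at -0.94 (SE 0.15), were lower. Tead4 was not called at -0.33 (SE 0.14, adjusted p = 0.0596), but was without YAP-S127A replicate 3 (0.0333). It was also called without the second ID series (0.0329), with it as a covariate (0.032), with only the groups compared (0.0449) and without the least correlated library of each group (0.0221, range 0.0221 to 0.199 over 21 alternatives). Ccn1 was barely called at 0.52 (SE 0.21, adjusted p = 0.0499), and not without any of 8 single libraries: YAP-5SA replicate 1 (0.118), 2 (0.0526) or 3 (0.105), YAP-S127A replicate 1 (0.0911), 2 (0.132) or 3 (0.126) and TAZ-S89A replicate 1 (0.0533) or 5 (0.0505). The call was also lost with RLE (0.0647) or upper-quartile factors (0.0789), limma-voom (0.0549), no filter (0.0758), the strict filter (0.0573) and without the least correlated library of each group (0.135), in a range of 0.0034 to 0.135 over 21 alternatives. YAP/TAZ-TEAD targets went 7 up and 7 down of 22 (camera adjusted p = 0.511), with tissue factor, F3 (3.82, SE 0.21), and Igfbp3 (3.60, SE 0.25) higher and Rbms3 (-8.02, SE 0.24) lower. Hippo pathway components went 7 up and 5 down of 25 (camera adjusted p = 0.999), with the scaffold genes Wwc1 (1.84, SE 0.18) higher and Sav1 (-1.11, SE 0.14) lower.

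Mesenchymal genes fell in 26 of 30 cases and rose in 2 (camera adjusted p = 2.67e-11, and adjusted p = 0.00321 with an estimated correlation). The most affected were Tagln (-9.07, SE 0.89), Fstl1 (-8.97, SE 0.42), Pdgfrb (-8.72, SE 0.26) and smooth muscle actin, Acta2 (-7.33, SE 0.47). Of 19 epithelial genes, 11 rose and 1 fell (camera adjusted p = 0.00589, and adjusted p = 0.076 with an estimated correlation), with Krt8 (4.38, SE 0.37) and Krt18 (4.10, SE 0.31) higher. The cadherin Cdh1 went the other way, with fewer CPM in every YAP-5SA library than in every YAP-S127A library. A further 7 epithelial genes had too few counts to test, none above a pooled 0.44 CPM in any group. The list therefore does not show a rise of epithelial genes in general. Biliary and progenitor markers went 14 up and 3 down of 22 (camera adjusted p = 0.0157, and adjusted p = 0.128 with an estimated correlation), with the hemidesmosomal integrin Itgb4 (4.92, SE 0.22) and Krt19 (4.62, SE 0.38) higher and the water channel Aqp1 (-6.42, SE 0.28) lower. NRF2 targets rose in 20 of 22 cases and fell in 0 (camera adjusted p = 6.22e-08, and adjusted p = 0.186 with an estimated correlation), with Nqo1 (5.21, SE 0.30) and Mgst1 (4.42, SE 0.24) higher. In the p53 list, 17 of 22 rose and 3 fell (camera adjusted p = 0.00139, and adjusted p = 0.239 with an estimated correlation), including Fas (3.89, SE 0.24), Perp (3.84, SE 0.34) and Mdm2 (2.87, SE 0.25). Inflammatory cytokines and chemokines went 18 up and 6 down of 30 (camera adjusted p = 0.0227, and adjusted p = 0.149 with an estimated correlation). Csf2 (4.70, SE 0.34) was higher, although Il11 (-7.14, SE 0.29), Cxcl12 (-6.79, SE 0.34) and Il6 (-6.18, SE 0.34) were far lower.

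Macrophage and leukocyte markers rose in 13 of 17 cases and fell in 1 (camera adjusted p = 0.000196, and adjusted p = 0.0454 with an estimated correlation). Levels were low, with C1qa at 2.501 ± 0.690 CPM in YAP-5SA and 0.0185 ± 0.0321 in YAP-S127A, and C1qc at 1.37 ± 0.1598 with no count in YAP-S127A (at least 50.5-fold higher). In all, 17 lists were not called, with adjusted p from 0.0633 to 0.999. Oncofetal liver genes (3 higher, 7 lower and 4 not called) became called without YAP-5SA replicate 1 (0.0378, range 0.0378 to 0.0919 over 14 alternatives). Stress response genes (1 higher, 10 lower and 12 not called) were called without YAP-5SA replicate 2 (0.0211) or the least correlated library of each group (0.0282, range 0.0211 to 0.204 over 14 alternatives). Adjusted over the list alone, 19 of the 25 lists gave the same counts. The others became 15 and 3 for biliary, 3 and 4 for stellate, 2 and 5 for endothelial, 3 and 1 for proliferation (from 7 and 1), 7 and 6 for Wnt and 9 and 10 for AP-1 genes. Median, mean and test differed in sign for Hippo (-0.09, 0.03, higher), hepatocyte (-0.01, -0.17, higher), Notch (0.12, -0.38, lower), Wnt (0.21, -0.20, higher) and AP-1 genes (0.29, -0.34, higher).

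By pooled counts the keratin Krt76 was higher in YAP-5SA by 5641-fold (95% counting interval 1561 to 46584, from 2 counts) and Tnip3 by 3165-fold (95% counting interval 568 to 125050.0, from 1 count). Dmkn was higher by 2091-fold (95% counting interval 375 to 82627, from 1 count) and Fam3b by 1478-fold (95% counting interval 409 to 12208, from 2 counts). The other large increases were those of Aldh3a1 (11.36, SE 0.52) and Sprr2h (9.60, SE 0.27), a member of a family of similar genes. The urotensin gene Uts2b (Entrez gene 224065, chromosome 16, 27353322 to 27370239) was at 37.5 ± 0.738 CPM in YAP-S127A with no count in YAP-5SA (at least 1506.1-fold lower). The receptor Il1rl2 (at least 935.8-fold lower) and the homeobox gene Mnx1 (at least 824.3-fold) had none there either. Meg3, an imprinted noncoding RNA, was lower by 6622-fold (95% counting interval 1833 to 54690.0, from 2 counts) and Sh2d6 by 6242-fold (95% counting interval 1119.9 to 246580.0, from 1 count). The mechanosensitive channel Piezo2 (-12.28, SE 0.41) was also lower. Meg3 overlaps Mir1906-1 and Piezo2 overlaps Gm36651, so these counts are uncertain. EdgeR called 10061 genes, 5145 higher and 4916 lower in YAP-5SA, 6269 of them by at least 1 on the log2 scale.

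Fold changes also shifted by whole chromosomes. Among genes with a mean log2 CPM of at least 2, the median on chromosome 7 was -0.67 for TAZ-S89A against YAP-S127A and -0.54 against YAP-5SA, with -0.64 and -0.57 on chromosome 9. Chromosome 17 had medians of 0.95 for TAZ-S89A against YAP-5SA and -0.69 for YAP-5SA against YAP-S127A, and chromosome 4 of 0.53 and -0.53. The shift on chromosome 14 began within it, near position 45134448, where window medians against YAP-S127A went from 0.24 to -0.77. Removing each gene's chromosome median moved the median of p53 targets against YAP-5SA from -1.89 to -1.57, and against YAP-S127A from -0.99 to -0.41. It moved that of mesenchymal genes in YAP-5SA against YAP-S127A from -3.44 to -3.70. For hepatocyte markers in TAZ-S89A against YAP-S127A it went from -1.54 to -1.06, and for YAP/TAZ-TEAD targets from -0.61 to -0.43. Against YAP-5SA the medians of these lists went from -2.42 to -2.29 and from -0.73 to -0.45.

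**Figure D3:**
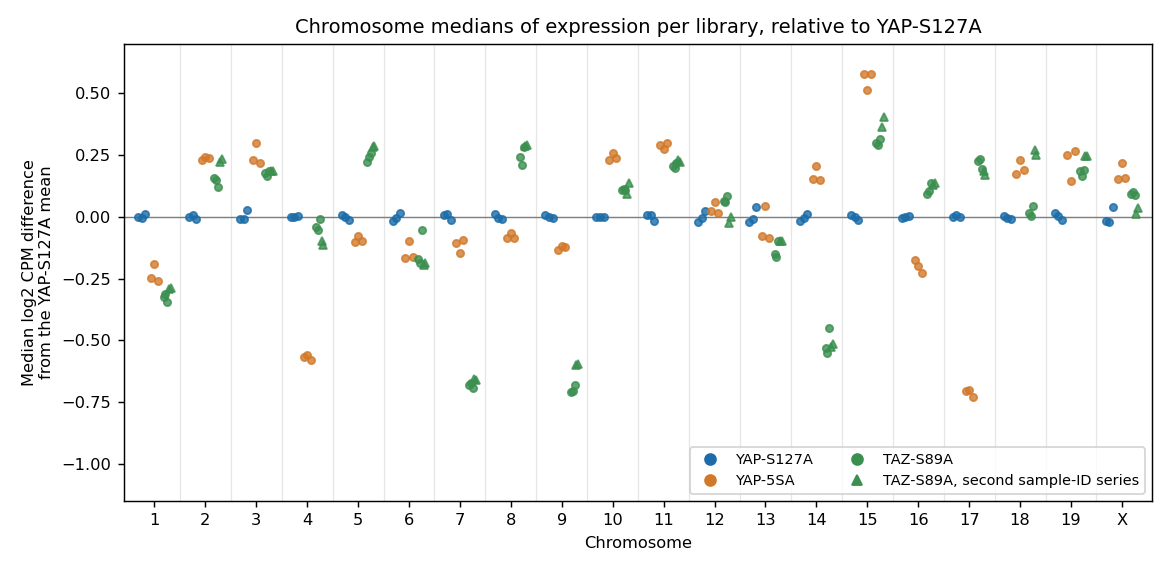
Median over the genes of each chromosome of the log2 CPM difference from the YAP-S127A mean, with each point a library. The 5 TAZ-S89A libraries lie lowest on chromosomes 7 and 9, and the 3 YAP-5SA libraries on chromosomes 4 and 17.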

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

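The tests on p53 targets below were chosen only after the result was seen. Within TAZ-S89A, the only group of more than 3 libraries, 22 of 162 values, taken over the named genes and the lists, had a library far from the other 4. The gap over the range was above Dixon's 95% critical value, which chance exceeds in about 1 in 20 groups, and genes of a library are not independent. Replicate 3 was that library in 15 of them. It stood high for Ccng1 (161 CPM, others 108 to 114), Cyp51 (316 CPM, others 173 to 179), Ephx1 (79.3 CPM, others 50.9 to 53.7), Fstl1 (164 CPM, others 83.7 to 100), Igfbp3 (199 CPM, others 122 to 137) and Mdm2 (114 CPM, others 75.2 to 84.5). It stood low for Rbms3 (3.92 CPM, others 5.3 to 5.48), Sh2d6 (0.029 CPM, others 0.122 to 0.142), Tead1 (78.1 CPM, others at least 114) and Cbx5 (423 CPM, others 559 to 611). In mean log2 CPM of a list, replicate 3 was at 4.13 for biliary and progenitor markers (others 3.96 to 4.01), 2.05 for epithelial genes (others 1.85 to 1.9), 6.07 for cholesterol synthesis (others 5.69 to 5.74), 5.25 for p53 targets and cell cycle inhibitors (others 4.9 to 4.97) and 11.2 for sex-linked genes (others 12.1 to 12.3). Among other libraries, TAZ-S89A replicate 2 was at 0.111 CPM of Lin28b (others 0 to 0.0236) and TAZ-S89A replicate 4 was at 2.49 CPM of Peg3 (others 1.54 to 1.72). The rest were genes with counts in a single TAZ-S89A library and 0 in the others: Adm at 0.0223 CPM in replicate 2, Ano3 at 0.0418 CPM in replicate 5, Anxa10 at 0.0408 CPM in replicate 4, Il1rl2 at 0.0446 CPM in replicate 2 and Ctss at 0.0418 CPM in replicate 5. No explanation of these single libraries was tested.

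The list of p53 targets and cell cycle inhibitors also holds Trp53 itself and the CDK inhibitor Cdkn2b. It was called lower in TAZ-S89A against YAP-5SA (camera adjusted p = 0.000196) and against both YAP groups (0.00144), calls that an estimated correlation ended (0.192 and 0.239). Lower Trp53 mRNA was argued against, since its log2 fold change against both YAP groups was 0.41 (SE 0.13), upwards. That rise came mostly from YAP-S127A. Trp53 was at 150.1 ± 27.9 CPM in TAZ-S89A and 89.28 ± 5.43 in YAP-S127A, but at a similar 143.0 ± 10.8 in YAP-5SA. Subtracting each chromosome's median moved the median of all 22 members against YAP-5SA from -1.89 to -1.57 (SE 0.48), which argues against chromosome-wide shifts as the whole cause there, but against YAP-S127A it went from -0.99 to -0.41 (SE 0.30), a difference that such shifts may explain at least in part. High levels in YAP-5SA alone were argued against for most members, since against YAP-S127A 14 of 22 were called lower and 4 higher. The list mean was at most 5.25 log2 CPM in a TAZ-S89A library and at least 5.625 in a YAP-S127A library. Whether the list fell more than other genes stayed undecided, as it was not called against YAP-S127A (camera adjusted p = 0.0642, or 0.0436 without TAZ-S89A replicate 3, range 0.0401 to 0.0941 over 14 alternatives, and 0.634 with an estimated correlation). A loss of p53 function that leaves its mRNA in place, differences between lines whatever the mutant and an effect of TAZ-S89A itself stay open and were not tested.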

How the results depend on the processing

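Leaving out the library of each group that correlates least with the others was chosen only after the result was seen. The numbers of called genes kept within 1.5 times of the reported ones under every alternative run except the requirement of an absolute log2 fold change of at least 1, which by its construction removes small changes. With it, 5122 genes were called for TAZ-S89A against both YAP groups, 5873 against YAP-S127A, 6164 against YAP-5SA and 6269 for YAP-5SA against YAP-S127A. Leaving out each library in turn gave 10044 to 11157, 9020 to 10920, 9451 to 11154 and 8778 to 10724 genes, in the same order of comparisons. The lowest were without YAP-S127A replicate 2, YAP-S127A replicate 1, YAP-5SA replicate 1 and YAP-S127A replicate 1. The strict low-count filter, which tests fewer genes, gave 7970, 7694, 7780 and 7383, of which 7818, 7591, 7661 and 7271 were among the genes reported. The highest counts were 11498 and 11506 with no filter, for TAZ-S89A against both YAP groups and against YAP-5SA, and 11250 and 11782 with the ID series as a covariate, for the others. Without the least correlated library of each group they were 10685, 10302, 10392 and 9379. Over the alternatives that keep all effect sizes, higher genes made up 46.2% to 51.3%, 45.1% to 51.1%, 44.9% to 49.9% and 48.6% to 52.5% of calls.

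Of the values of named genes under the alternatives fixed before the data were examined, 8808 kept their direction and stayed called or uncalled as before. A further 69 lost the call and 9 gained it, and none reversed. For list tests the numbers were 1292, 39 and 13, with none reversed. Under the added alternative, 442 values of genes stayed called or uncalled as before, 11 lost the call and 2 gained it, and for lists 92, 1 and 3. With an estimated correlation 5 of the 27 called list tests remained called. That estimate lay under the preset 0.01 for hepatocyte (-0.0199), oncofetal (0.00767), epithelial (-0.00575), mesenchymal (-0.0254), macrophage (-0.0274), biliary (0.00756) and inflammatory lists (0.00993). Calls lost in those lists therefore do not reflect a higher correlation between genes. It was above 0.01 for cholesterol synthesis (0.169), proliferation (0.315), p53 (0.125), NRF2 (0.273) and stress genes (0.372). The proliferation list in TAZ-S89A against both YAP groups had adjusted p from 0.0129 to 0.069 over 14 alternatives, NRF2 targets against YAP-S127A from 0.0214 to 0.107 over 14 alternatives, and the stress response list from 0.0102 to 0.0597 over 14 alternatives. The cause was not tested.

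Within TAZ-S89A, a term for the second ID series called 4666 genes, 1984 higher and 2682 lower in replicates 4 and 5, 1575 of them by at least 1 on the log2 scale. Neither YAP group has libraries in that series, so it cannot be separated from differences between TAZ-S89A lines. Of 135 tested genes with values in the text, 37 were called by that term, 13 of them by at least 1. The median of chromosome 18 relative to YAP-S127A was 0.27 and 0.25 in replicates 4 and 5 and under 0.05 in replicates 1 to 3. No paired analysis was possible because the labels give no replicate numbers. In simulated counts a true 1.5-fold change was recovered in 20.4% of genes for TAZ-S89A against both YAP groups. The share was 19.6% and 16.3% for TAZ-S89A against YAP-S127A and against YAP-5SA, and 8.2% for YAP-5SA against YAP-S127A. Most simulated genes were unchanged, 17550 of 17776 in the first contrast, whereas 10699 of 18224 genes were called in the data. The adjusted cutoff was therefore stricter in the simulation, and these shares do not measure how many small changes the data miss.

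Regrouping the libraries at random was also run. For TAZ-S89A against both YAP groups, 1 of 100 splits drawn from 4620, the real one, called as many genes (10699, highest other 6815). That other split kept TAZ-S89A together and mixed the YAP groups. For TAZ-S89A against YAP-S127A it was 1 of 56 (10505, highest other 2070) and against YAP-5SA 1 of 56 (10545, highest other 2654). No other split that was run called as many genes. The splits treat all libraries as exchangeable, whereas those of a group may be cultures of a single line. Chance differences between lines therefore cannot be excluded as the source of these counts. In both pairwise cases the highest other split set TAZ-S89A replicates 1 to 3 against the other libraries of the pair, which separates the TAZ-S89A libraries by ID series but not the others. For YAP-5SA against YAP-S127A the 10 splits, of which 1 called as many genes, are too few for a share under 0.05 (real value 10061, highest other 0).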

Other observations

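The tests in this part were chosen only after the result was seen. Of 60 chromosome medians in the 3 pairwise comparisons, 45 differed from expression-matched gene sets at an adjusted p under 0.05. Expression level was argued against on chromosomes 7 and 9, whose largest adjusted p in the TAZ-S89A comparisons was 0.0002. A few regions were argued against too, since all 36 of 36 windows of at least 40 neighbouring genes there lay beyond 0.5 times the chromosome's median in both comparisons. A different copy number of whole chromosomes or large segments may explain the shifts: medians of windows over 50 Mb apart on a chromosome correlated at r = 0.837, 0.812 and 0.747 for TAZ-S89A against YAP-S127A, TAZ-S89A against YAP-5SA and YAP-5SA against YAP-S127A (792 pairs of 282 windows, which are not independent, permutation p = 0.0001, the smallest that the permutations can give, highest permuted r 0.17). The correlation shows the same chromosome-wide shifts again, so it cannot tell copy number from another cause that acts along a chromosome. No DNA was analysed here.

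On chromosome 16 window medians of TAZ-S89A against YAP-5SA went from 0.05 to 0.99 near position 38346983, and on chromosome 14 those against YAP-S127A went from 0.24 to -0.77 near 45134448. In YAP-5SA against YAP-S127A the median of chromosome 15 was 0.64.

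Macrophage markers were higher in YAP-5SA at low levels. Of the 11 tested markers under 1 CPM in both other groups, 8 were higher in every YAP-5SA library than in every other library, but Ptprc, Fcer1g and Aif1 were not. Macrophages mixed into those libraries may be the source, and cannot be told apart from expression by the tumour cells, as every YAP-5SA library showed it. Of abundant macrophage transcripts, YAP-5SA held Cd74 at 9.13 ± 1.62, Lyz2 at 15.96 ± 4.39 and Ctss at 2.91 ± 0.0887 CPM. Apoe was at 7.11 ± 0.342 CPM there and 16.6 ± 0.809 in YAP-S127A.

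TAZ-S89A libraries held almost no Hoxb and Hoxc transcripts. The 9 tested Hoxb genes (chromosome 11, 96194316 to 96354020) summed to 0.28 CPM in TAZ-S89A, 348 in YAP-5SA and 34.5 in YAP-S127A. The 9 tested Hoxc genes (chromosome 15, 102921131 to 103036856) summed to 0.07, 297 and 36.99 CPM. Beside Hoxb, Ttll6 was at 2.03 ± 0.639 CPM in TAZ-S89A, 5.24 ± 1.05 in YAP-5SA and 1.13 ± 0.367 in YAP-S127A, and Skap1 at 1.45 ± 0.571, 10.7 ± 1.24 and 2.21 ± 0.253. Beside Hoxc, Smug1 was at 50.1 ± 7.96, 59.8 ± 1.55 and 44.4 ± 2.05 CPM, and Cbx5 at 552 ± 75.4, 505 ± 56.7 and 328 ± 11.9. The imprinted noncoding RNAs Meg3, Rian and Mirg of chromosome 12 were at 109.6 ± 7.12, 42.6 ± 4.67 and 2.23 ± 0.104 CPM in YAP-S127A and under 0.3 CPM in the other groups. Cdkn2a was at 176 ± 109 CPM in TAZ-S89A, 126.7 ± 37.0 in YAP-5SA and 48.8 ± 11.5 in YAP-S127A. Gapdh was at only 12.9 ± 1.75, 8.15 ± 1.63 and 15.2 ± 1.54 CPM in the same order, in counts that hold unique alignments only.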
